A study of Homo sapiens with 6 samples.

How the data were processed

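Total RNA of MCF10A cells, extracted with phenol and chloroform after 24 h in 35 mm dishes, was labelled with biotin from an input of 200 ng and hybridised to Affymetrix HG-U133 Plus 2 arrays, per the labels' protocols. The medium held 5% horse serum, 20 ng/ml EGF, 0.5 μg/ml hydrocortisone, 100 ng/ml cholera toxin and 10 μg/ml insulin. There were 6 arrays, 1 for each number of cells plated, and each array's density was taken from its label. Whether an array holds RNA of 1 dish or of several is not given in the sources used here.

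The submitters' processing notes name RMA, without a version; RMA corrects background, normalizes between arrays and summarises the probes of each probe set. The deposited values are linear ratios of each probe set to the 50K array: all 54675 values of the 50K column equal 1 within a tolerance of 1e-06, and the other values lie between 0.0292 and 98.5. The step that divided by the 50K array is not given in the sources used here, nor is the scaling between arrays beyond the name RMA. No array intensity was used here, so signal over background is unknown, and the fall of a gene that reached the background of the array is understated.

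The design fixed before the data were examined assumed log2 values with a level. Ratios carry none, so the following settings took its place. The log2 of each ratio was used without a filter on low values, a gene was the mean of all its probe sets instead of the brightest, and the variance model had no mean-variance trend. Dividing a gene by its 50K value shifts all 6 of its log2 values by the same amount and leaves the slope, the quadratic term and their residuals unchanged, so the 50K array entered the fits like the others.

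Of the 54675 probe sets, 62 were controls, which were left out of the gene values. Among all probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 were not listed there; only those with 1 symbol were used for genes. Of the 41097, the gene identifiers of 41043 were found in the RefSeq gene table and 54 kept the annotation's symbol; 0 symbols changed. This gave 19775 genes, 9252 with 1 probe set and 10523 with several. Of 6 reference genes fixed in advance, 1 was not analysed here.

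Trends were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as the slope of the log2 ratio on log2 of the cells plated, with 4 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Curvature was the quadratic term of an orthogonal polynomial with 3 residual degrees of freedom. Errors after ± are standard errors of these fits. Since there are no replicates, the residuals mix the variation between dishes, technical noise and any departure from a line. Differences of 2-fold or more between single arrays were counted without a test.

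The 40 gene lists, of which 4 hold markers of fibroblasts, endothelial cells, leukocytes and adipocytes, were fixed before the data were examined. They were tested on the slope with limma's camera at a preset correlation of 0.01, with the correlation estimated from each list, with fry, and with a two-sided exact permutation of the 6 cell numbers over all 720 orders for the list mean, each adjusted over the 40 lists. The genes named were set by a rule fixed before the data were examined. It takes the 12 rising and 12 falling genes with the largest slopes among those past the threshold that kept their sign when each array was left out. It adds up to 4 members with the largest slopes of each list that passed and up to 2 of other lists, the 2 smallest p-values for curvature if none passed, the 2 largest rises and falls per step, and the reference genes. The rest were named after their values were seen: the list members that moved against their list, further members of the ATF4 list, and those of the gene families and of the tests in the closing part.

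Alternatives were leaving out probe sets whose identifiers mark possible cross-hybridisation (the suffixes _x_at and _s_at), centring the arrays on their medians, the cell number itself or its rank instead of its log2, the 3 lowest against the 3 highest densities, and leaving out each array in turn. Drawing 1 probe set per gene at random, robust variance estimates, a set test of the quadratic term and testing each probe set alone were added after the data were examined. Poly-A controls, added to RNA before labelling, were read as signs of labelling, also after the data were examined.

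The procedures were tested on simulated data with the residual spread of the 19775 genes. For the density trend, 78% of 100 genes changed by 2-fold over the range and 94% of 100 genes changed by 4-fold were recovered, with 7 unchanged genes called. For curvature, 79% of 200 genes with a quadratic term of 1 were recovered. Random values gave 52 strictly ordered genes against 54.9 expected, and all 3 changed lists of the simulation were recovered at the preset and at the estimated correlation. Genes were simulated independently of each other, so this tests neither the gene tests nor the list tests under the correlation between genes in the data. The recovery and the number of unchanged genes called hold for independent genes only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.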

Results

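The transcriptome of MCF10A, an established non-tumorigenic line of human breast epithelial cells, was measured at 6 plating densities. Between 50K and 800K cells were seeded per 35 mm dish, a 16-fold range, and RNA was taken after 24 h of culture. Each density was measured on 1 Affymetrix HG-U133 Plus 2 array, so no density has a replicate. The p-values of single genes come from the scatter of the 6 arrays around a fitted line or curve. Those of camera compare the genes of a list with the other genes, and those of the exact permutations come from orders of the cell numbers. The preset setting of camera assumes a correlation of 0.01 between the genes of a list. The correlations estimated from the lists lay between −0.0541 (Notch) and 0.874 (DNA replication). Correlation is not the whole difference between the preset and the estimated setting. For YAP/TAZ targets the estimate was −0.00539, under the preset, yet the unadjusted camera p was 0.00346 against 2.12e-08 at the preset. The arrays are named here by the number of cells plated. Each deposited value was the ratio of a probe set to its value on the 50K array, which gives changes but no absolute level, and the number of arrays limits the precision. Median ratios over all non-control probe sets lay between 1.013 and 1.036 on the other 5 arrays. The samples were numbered in order of density. The processing order is not given in the sources used here, and if it followed these numbers, a drift along it would follow density too.

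The comparison the series was built for, how expression changes with cell density, was fitted as the slope of log2 expression per doubling of the cells plated. KRT15, TGM1 and SERPINA3 were among the genes that rose most. KRT15, a keratin of basal cells of stratified epithelia, rose by 1.51 ± 0.03 log2 units per doubling (SE, 6 arrays) and was 59.9-fold higher at 800K than at 50K. The slope of TGM1, the transglutaminase that crosslinks the cornified envelope, was 1.20 ± 0.04, that of the protease inhibitor SERPINA3 was 1.19 ± 0.09, and that of ZNF750, a transcription factor of epidermal differentiation, was 1.08 ± 0.15. S100A8 and S100A9, the subunits of calprotectin, rose with slopes of 1.04 ± 0.16 and 0.94 ± 0.13 and were 15.7-fold and 13.2-fold higher at 800K. The other 6 of the 12 steepest rising genes were BBOX1, an enzyme of carnitine synthesis (slope 1.29), the lipoxygenase ALOX15B (1.02), the receptor FGFR3 (1.00), the oestrogen sulfotransferase SULT1E1 (1.00), the transporter ABCA6 (0.96) and the secretoglobin SCGB1A1 (0.94; adjusted p = 0.0532 without the 100K array).

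Among falling genes the steepest was SCG5, a chaperone of prohormone convertase, with a slope of −1.21 ± 0.24. It was 29.0-fold lower at 800K than at 50K, and its ratio was already 0.0352 at 200K. The call of SCG5 was lost without the 50K array (slope −0.85, adjusted p = 0.144), the 100K array (0.0649) or the 600K array (0.052). PTX3, a secreted pattern-recognition protein, had a slope of −0.90 ± 0.02 and was 12.7-fold lower at 800K. PMEPA1, an inhibitor of TGF-beta signalling that is itself induced by it, had a slope of −0.87 ± 0.03, and CCN2, a matricellular protein and target of the YAP and TAZ coactivators, had a slope of −0.78 ± 0.04 and was 7.09-fold lower at 800K. The remaining 8 of the 12 steepest falling genes were the phospholipase PLCB4 (−0.94), CCBE1 (−0.88), the adhesion protein AMIGO2 (−0.88), the protease inhibitor SPINK6 (−0.87), the interleukin receptor IL7R (−0.86), INSC (−0.86), the sphingosine kinase SPHK1 (−0.82) and the scaffold protein AKAP12 (−0.79). The adjusted p of these 24 genes lay between 2.06e-05 and 0.0182.

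**Figure D1:**
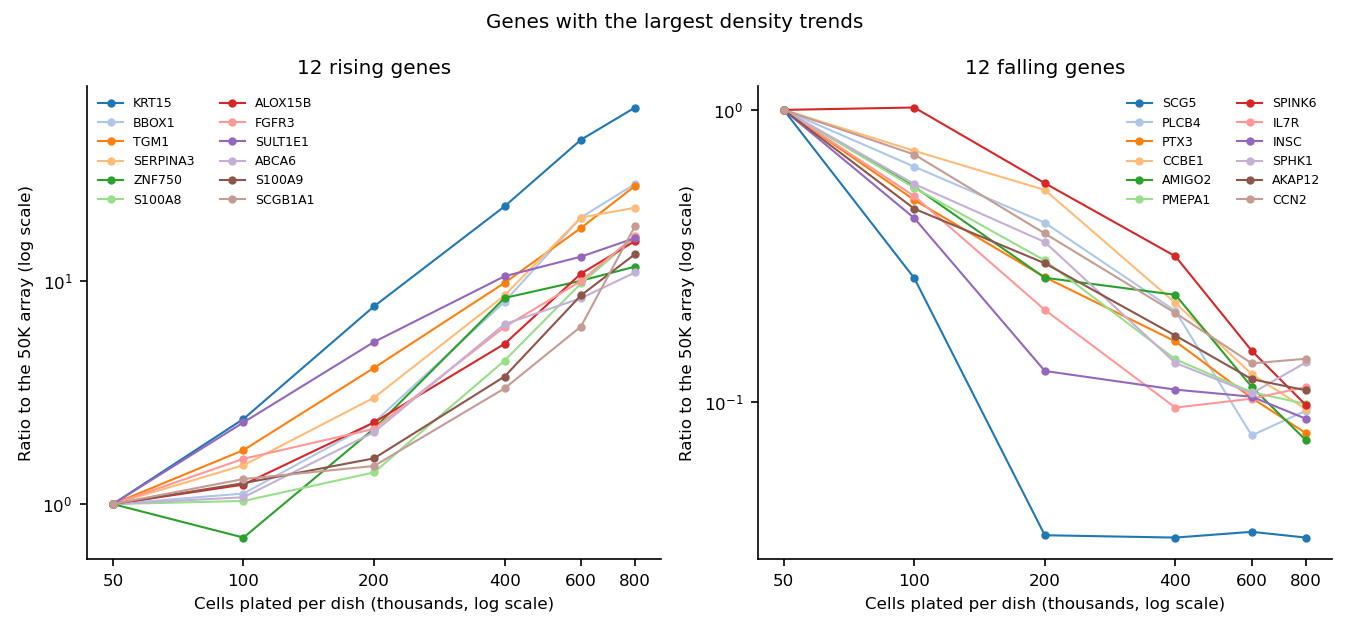
Ratio to the 50K array (vertical axis, log scale) against the number of cells plated (log scale) for the 12 steepest rising genes (left) and the 12 steepest falling genes (right), 1 point per array. KRT15 reached 59.9 at 800K, and SCG5 was flat from 200K on.

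Across all 19775 genes tested, 4220 (21.3%) had a slope with an adjusted p under 0.05 in limma, of which 1765 rose and 2455 fell. The fitted change between 50K and 800K was 2-fold or more for 901 of them, 409 rising and 492 falling, and the median size of the change among all 4220 was 0.62 log2 units. The count was 2664 when probe sets prone to cross-hybridisation were left out, 2447 without the 600K array and 2388 without the 800K array. Of 2713 called genes measured by more than 1 probe set, 2117 had all probe sets moving the same way.

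The lists of DNA replication, G2/M and ribosome biogenesis passed camera in the falling direction and that of quiescence in the rising one, at the preset correlation. Of 31 measured genes of DNA replication and S phase, 25 fell, none rose and 6 did not pass the test; 30 fell when adjusted over the list alone. Without the 100K, 600K or 800K array 9, 9 and 11 of the 31 fell. CCNE2, a cyclin of S phase entry, had a slope of −0.68 ± 0.11, the ribonucleotide reductase subunit RRM2 −0.61 ± 0.11, the replication factor MCM10 −0.59 ± 0.11 and the origin licensing factor CDC6 −0.58 ± 0.11. The list mean was 0.377 of its 50K level at 800K (camera adjusted p = 6.33e-13, and adjusted p = 0.38 with an estimated correlation). Of 30 genes of G2/M and mitosis, 20 fell and 10 did not pass, with 25 falling when adjusted over the list alone; without 100K, 600K or 800K the number was 7, 7 and 8. Examples were the mitotic kinase AURKB (−0.49 ± 0.05), the activator of the anaphase-promoting complex CDC20 (−0.39 ± 0.06), ANLN (−0.33 ± 0.06) and BIRC5 (−0.33 ± 0.06). This list gave a camera adjusted p of 8.01e-11, and an adjusted p = 0.389 with an estimated correlation. Genes of ribosome biogenesis and MYC targets included 10 that fell and 10 that did not pass, with 12 falling when adjusted over the list alone and 6, 6 and 5 without 100K, 600K or 800K (camera adjusted p = 1.54e-06, and adjusted p = 0.38 with an estimated correlation). Among them were UTP4 (−0.28 ± 0.05) and the polyamine enzyme ODC1 (−0.27 ± 0.04). Of 18 inhibitors of cyclin-dependent kinases and genes of quiescence, 9 rose and 9 did not pass, with 11 rising when adjusted over the list alone. TXNIP, a thioredoxin-binding arrestin, had a slope of 0.58 ± 0.08, PDCD4 0.58 ± 0.06, the inhibitor CDKN1C 0.54 ± 0.02 and YPEL3 0.32 ± 0.08 (camera adjusted p = 4.33e-06, and adjusted p = 0.24 with an estimated correlation). Without the 100K, 600K or 800K array the adjusted p was 0.0588, 0.057 and 0.0615 for MCM10, 0.0587, 0.0552 and 0.0531 for CDC6 and 0.103, 0.1 and 0.128 for YPEL3. It was 0.0521 for YPEL3 without 400K and 0.0504 for UTP4 without 800K.

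The lists of YAP/TAZ targets, actin, mesenchymal genes and TGF-beta targets also passed camera in the falling direction at the preset correlation, while the basal lamina list did not pass (camera adjusted p = 0.627). Of 23 targets of YAP/TAZ and TEAD factors, which respond to cell shape and contact, 17 fell, 3 rose and 3 did not pass; adjusted over the list alone, 18 fell and 3 rose. After CCN2, the largest slopes were those of tissue factor F3 (−0.71 ± 0.04), CCN1 (−0.71 ± 0.06) and the ectonucleotidase NT5E (−0.43 ± 0.06). The members that rose were ARHGEF17, PTPN14 and RBMS3. The list mean at 800K was 0.5 of that at 50K (camera adjusted p = 1.41e-07, and adjusted p = 0.0803 with an estimated correlation). In the list of actin cytoskeleton genes and SRF targets, 13 of 24 fell, 1 rose and 10 did not pass, with 14 falling and 1 rising when adjusted over the list alone. The myosin light chain MYL9 had a slope of −0.34 ± 0.05, the myosin heavy chain MYH9 −0.28 ± 0.02, FHL2 −0.20 ± 0.02 and TAGLN −0.39 ± 0.08. For TAGLN 1 of 3 probe sets had a slope of the other sign, and without the probe sets prone to cross-hybridisation its slope was 0.01. The member that rose was CALD1, an actin-binding protein. The camera adjusted p was 1.33e-05, with an adjusted p = 0.158 with an estimated correlation and an adjusted p of 0.253 without the probe sets prone to cross-hybridisation. Of 25 mesenchymal genes and genes of epithelial-mesenchymal transition, 9 fell, 2 rose and 14 did not pass, with 11 falling and 2 rising when adjusted over the list alone. The crosslinking enzyme gene LOX and S100A4 rose. THBS1 fell with a slope of −0.62 ± 0.05, fibronectin FN1 with −0.49 ± 0.02, TGFBI with −0.42 ± 0.02 and the gelatinase MMP9 with −0.41 ± 0.06 (camera adjusted p = 0.00297, and adjusted p = 0.354 with an estimated correlation). On the scale of the cell number itself the mesenchymal list gave an adjusted p of 0.0806. Of 23 TGF-beta and SMAD targets, 8 fell, 3 rose and 12 did not pass; adjusted over the list alone, 11 fell and 3 rose. Without 50K 5 fell, and without 100K, 600K or 800K 1 rose. Besides PMEPA1 and CCN2, the basement membrane collagen gene COL4A1 (−0.47 ± 0.03) and ID3 (−0.45 ± 0.03) had the largest slopes, and BHLHE40, JUNB and LTBP3 rose. CCN2 is also in the YAP/TAZ list. The camera adjusted p was 0.00075, with an adjusted p = 0.38 with an estimated correlation, 0.198 without the 50K array and 0.12 on the scale of the cell number itself. Calls of single genes were lost for TAGLN without 100K, 600K or 800K (adjusted p 0.0684, 0.0685 and 0.0684) and for MMP9 without 50K (0.0708). Among the members that rose they were lost for PTPN14 without 50K, 100K or 600K (up to 0.0765), CALD1 without 100K, 400K, 600K or 800K (up to 0.0845), LOX without 50K or 600K (up to 0.0607), JUNB without 100K, 400K, 600K or 800K (up to 0.118) and LTBP3 without 100K, 600K or 800K (up to 0.114).

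The lists of epithelial junctions and of keratinocyte differentiation passed camera in the rising direction at the preset correlation. Of 25 genes of adherens, tight and desmosomal junctions, 16 rose, 1 fell and 8 did not pass; adjusted over the list alone, 17 rose and 2 fell. The desmosomal cadherin gene DSG2 fell. The desmosomal cadherins DSG3 (0.67 ± 0.02) and DSC3 (0.41 ± 0.05) and the tight junction proteins CLDN7 (0.66 ± 0.06) and OCLN (0.47 ± 0.06) led the list, which gave a camera adjusted p of 9.81e-09 and an adjusted p = 0.111 with an estimated correlation. DSG3 was 6.32-fold and CLDN7 5.68-fold higher at 800K than at 50K. Of 33 genes of keratinocyte differentiation and the cornified envelope, 19 rose, 1 fell and 13 did not pass, with 22 rising and 1 falling when adjusted over the list alone. KRT15, which belongs to this list, is known from basal rather than cornified cells, and DMKN, a secreted epidermal protein, fell. The list mean was 2.88-fold higher at 800K (camera adjusted p = 1.6e-08, and adjusted p = 0.221 with an estimated correlation). With any 1 of the 6 arrays left out the call of DSG2 was lost (adjusted p up to 0.227, without 50K), and that of DMKN was lost without 800K (0.0517).

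**Figure D2:**
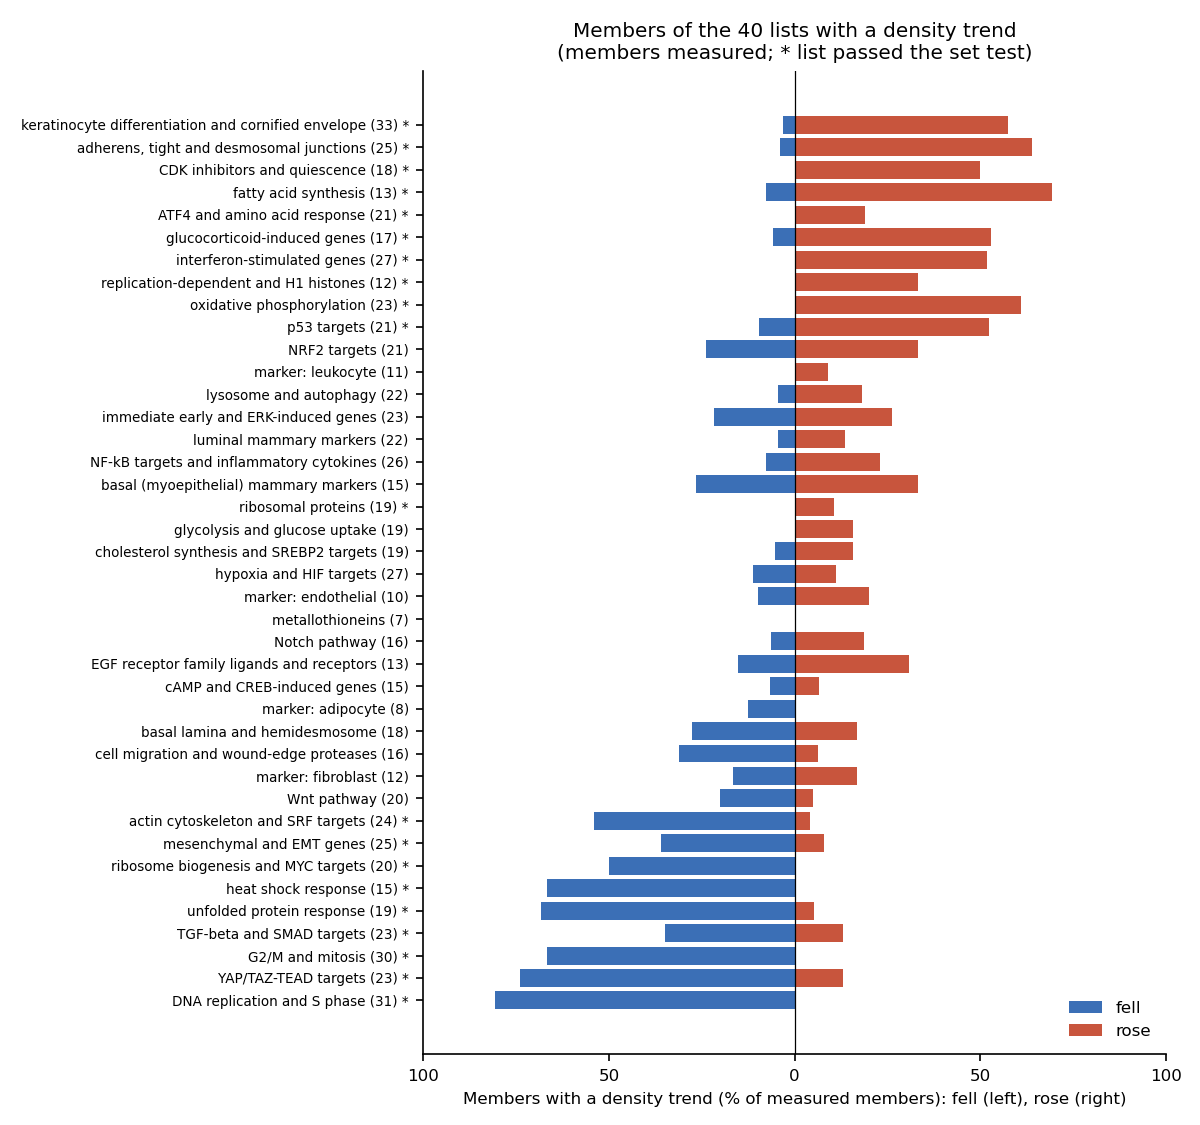
Share of the measured members of each of the 40 lists that rose (right) or fell (left) with density, in percent; the number of measured members follows each name and an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 pass with an estimated correlation. DNA replication and YAP/TAZ targets fell in 25 of 31 and 17 of 23 members.

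The lists of fatty acid synthesis, oxidative phosphorylation, interferon-stimulated and glucocorticoid-induced genes passed camera in the rising direction at the preset correlation. Of 13 genes of fatty acid synthesis, 9 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone and 5 rising without 50K, 100K or 600K. The acyl-CoA synthetases ACSL1 (0.54 ± 0.04) and ACSS2 (0.51 ± 0.04), the regulator SREBF1 (0.38 ± 0.04) and the desaturase SCD (0.34 ± 0.05) had the largest slopes, and GPAM, an acyltransferase of glycerolipid synthesis, fell. The camera adjusted p was 0.000385, with an adjusted p = 0.38 with an estimated correlation and an adjusted p of 0.0667 without the probe sets prone to cross-hybridisation. Of 23 genes of oxidative phosphorylation, 14 rose and 9 did not pass, with 16 rising when adjusted over the list alone, 7 without 50K and 8 without 800K. Their changes were small, as for COX7B (0.29 ± 0.02) and UQCRC2 (0.22 ± 0.04), and the list mean was 1.32-fold higher at 800K (camera adjusted p = 9.81e-09, and adjusted p = 0.158 with an estimated correlation). Of 27 interferon-stimulated genes, 14 rose and 13 did not pass, with 15 rising when adjusted over the list alone. IFI44L rose with a slope of 0.57 ± 0.03, OAS1 with 0.48 ± 0.07, IFIT1 with 0.47 ± 0.06 and IFI44 with 0.43 ± 0.04 (camera adjusted p = 6.82e-07, and adjusted p = 0.0803 with an estimated correlation). Of 17 glucocorticoid-induced genes, 9 rose, 1 fell and 7 did not pass; adjusted over the list alone, 10 rose and 1 fell. The culture medium contained hydrocortisone at every density. ZBTB16 (0.68 ± 0.03), glutamine synthetase GLUL (0.67 ± 0.07) and TSC22D3 (0.52 ± 0.04) rose and ANGPTL4 fell (−0.65 ± 0.10), with a camera adjusted p of 0.00019 and an adjusted p = 0.158 with an estimated correlation. The adjusted p of ANGPTL4 was 0.0625 without 50K and that of UQCRC2 0.0515 without 800K.

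Of 19 genes of the unfolded protein response, 13 fell, 1 rose and 5 did not pass, with 13 falling and 2 rising when adjusted over the list alone. The sensor gene ATF6 rose. SDF2L1 had a slope of −0.55 ± 0.06, the chaperone CALR −0.27 ± 0.05, the chaperone HSPA5 −0.27 ± 0.03 and MANF −0.25 ± 0.02 (camera adjusted p = 1.22e-05, and adjusted p = 0.158 with an estimated correlation). Of 15 heat shock genes, 10 fell and 5 did not pass; adjusted over the list alone, 11 fell and 1 rose. The co-chaperones DNAJA1 (−0.30 ± 0.04), FKBP4 (−0.27 ± 0.02) and STIP1 (−0.27 ± 0.04) were among them (camera adjusted p = 1.43e-05, and adjusted p = 0.221 with an estimated correlation). Of 21 p53 targets, 11 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone; without 50K, 600K or 800K 6, 5 and 6 rose. SESN1 rose with a slope of 0.29 ± 0.03, TP53INP1 with 0.22 ± 0.04 and GDF15 with 0.23 ± 0.05, while AEN and PLK2 fell. For GDF15 1 of 3 probe sets had a slope of the other sign, and without the probe sets prone to cross-hybridisation its slope was −0.01. The camera adjusted p was 0.00307, with an adjusted p = 0.221 with an estimated correlation and an adjusted p of 0.0628 without the probe sets prone to cross-hybridisation. Calls of single genes were lost for CALR without 100K, 600K or 800K (adjusted p 0.0638, 0.062 and 0.075), GDF15 without 50K, 100K or 600K (0.11, 0.0634 and 0.0612), ATF6 without 100K, 600K or 800K (up to 0.0817), AEN without any array but 200K (up to 0.105) and PLK2 without any but 50K (up to 0.105).

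Of 21 genes of the ATF4 and amino acid response, 4 rose and 17 did not pass, with 3 rising when adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, had a slope of 0.67 ± 0.11 and asparagine synthetase ASNS 0.46 ± 0.08. The list mean was highest at 400K: its log2 ratio was 0.03 at 200K, 1.02 at 400K, 0.74 at 600K and 0.22 at 800K. The set test of the quadratic term did not pass for this list (camera adjusted p = 0.625, and adjusted p = 0.967 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, was 11.5-fold above 50K at 400K and 2.09-fold above it at 800K, with an adjusted p of 0.241 for its slope. The camera adjusted p of the list was 0.0221, with an adjusted p = 0.779 with an estimated correlation and an adjusted p of 0.151 without the 100K array. It was also over 0.05 in 4 further alternatives with camera, between 0.0823 and 0.132, and fry gave an adjusted p of 0.271. Of 19 ribosomal proteins, 2 rose (RPL37, 0.17 ± 0.02, and RPL3, 0.10 ± 0.02) and 17 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00295, and adjusted p = 0.262 with an estimated correlation); without the probe sets prone to cross-hybridisation it was 0.0928. Of 12 histone genes, 4 rose and 8 did not pass, with the same counts adjusted over the list alone and 2 rising without 50K. H2AC6 (0.50 ± 0.07) and H2BC21 (0.27 ± 0.05) led the list (camera adjusted p = 0.0365, and adjusted p = 0.536 with an estimated correlation). Without the 100K or the 800K array the histone list gave adjusted p-values of 0.0567 and 0.0686, and in 3 further alternatives between 0.056 and 0.634. The adjusted p of RPL3 was 0.126, 0.0648 and 0.0774 without 50K, 600K or 800K, and that of H2BC21 0.0846 without 50K.

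**Figure D3:**
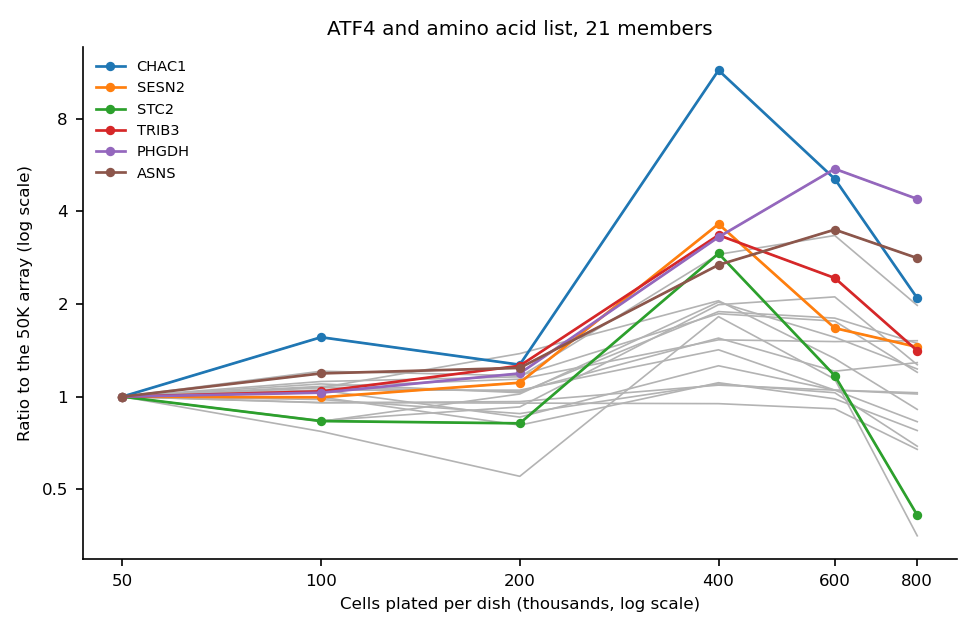
Ratio to the 50K array (vertical axis, log scale) of the 21 members of the ATF4 and amino acid list against the number of cells plated (log scale); each line is a gene, with 6 coloured and the others in grey. CHAC1 reached 11.5 at 400K.

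**Figure D4:**
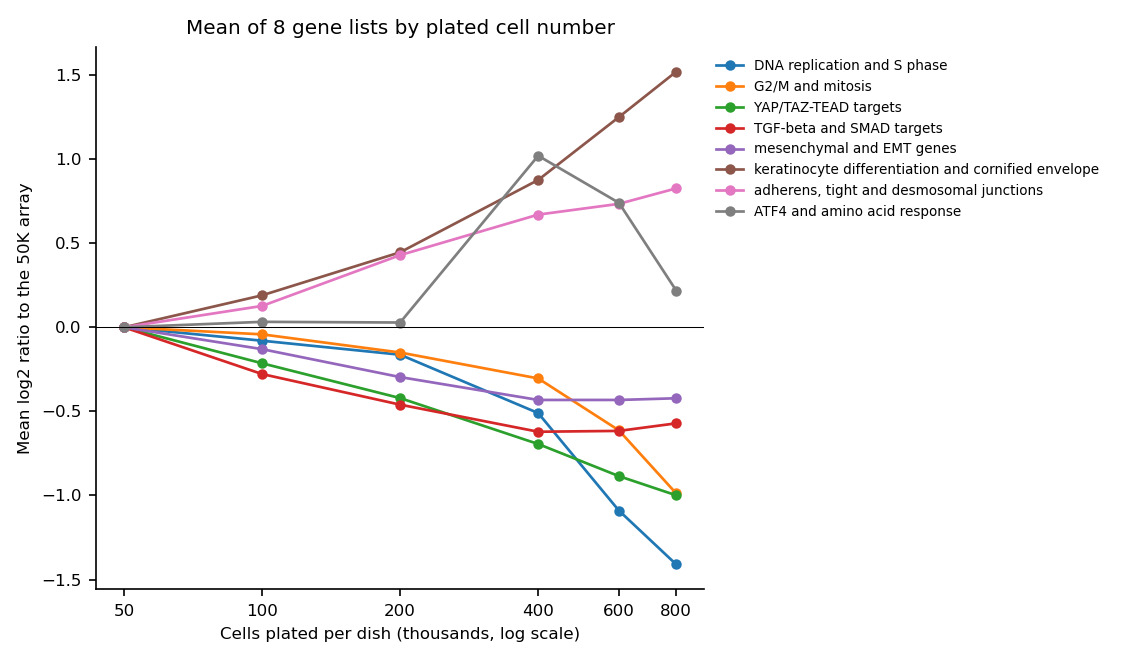
Mean log2 ratio to the 50K array (vertical axis) of 8 gene lists against the number of cells plated (log scale), 1 point per array. The ATF4 and amino acid list was highest at 400K, with 1.02, while the DNA replication list reached −1.41 at 800K.

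Of the 40 lists, 20 passed the camera test at the preset correlation of 0.01, 11 rising and 9 falling; with an estimated correlation camera passed 0, with 8 lists at an unadjusted p under 0.05. The test of whether a list's genes move on balance in 1 direction (fry), which does not compare them with other genes, passed for 26 lists, and an exact permutation of the 6 cell numbers for the list mean passed for 27. The smallest p that the 720 orders allow is 0.00139. Except for the metallothioneins, the lists that did not pass camera also held single genes with a trend. The luminal mucin MUC1 rose with a slope of 0.73 ± 0.01, the aldo-keto reductases AKR1B10 (0.83 ± 0.08) and AKR1C3 (0.62 ± 0.10) of the NRF2 list rose, and the Wnt antagonist DKK1 fell (−0.64 ± 0.07). The NRF2 list held 7 genes that rose and 5 that fell, with a mean slope of 0.08 and a median of −0.02 (camera adjusted p = 0.67); those that fell were FTL, GCLM, NQO1, SRXN1 and TXNRD1. The immediate early list, with FOS at 0.52 ± 0.13 and EGR3 at 0.49 ± 0.11, held 6 genes that rose and 5 that fell (camera adjusted p = 0.945). Without 100K, 600K or 800K 4 genes of the NRF2 list rose, and without 50K 3 fell. In the immediate early list 3 rose without 100K or 400K and 2 without 600K or 800K, and 3 fell without 50K. Calls were lost for FOS without 50K, 400K, 600K or 800K (adjusted p up to 0.213), EGR3 without 100K, 400K, 600K or 800K (up to 0.0799), NQO1 without any array but 200K (up to 0.21) and FTL without 50K (0.0596).

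The other lists that did not pass camera had these counts of genes that rose and fell. They were 3 and 5 of 18 for the basal lamina (COL4A2, −0.44 ± 0.04), 5 and 4 of 15 for basal mammary markers (MME, 0.48 ± 0.11), 3 and 1 of 22 for luminal markers (GATA3, 0.22 ± 0.02), 3 and 3 of 27 for hypoxia, and 3 and 0 of 19 for glycolysis (SLC2A3, 0.42 ± 0.07). Cholesterol synthesis had 3 and 1 of 19, NF-kB targets 6 and 2 of 26 (IL1RN, 0.28 ± 0.04), Notch 3 and 1 of 16 (HES1, 0.24 ± 0.02), and Wnt 1 and 4 of 20. The EGF receptor family had 4 and 2 of 13 (NRG1, −0.39 ± 0.04, but 0.00279 and no call for 1 random probe set), lysosome genes 4 and 1 of 22 (the protease CTSD, 0.46 ± 0.03), cAMP-induced genes 1 and 1 of 15, metallothioneins 0 and 0 of 7, and wound-edge proteases 1 and 5 of 16 (PLAT, 0.47 ± 0.03). Adjusted over the list alone, the basal lamina counts were 5 and 8, those of the NRF2 list 9 and 6, of hypoxia 6 and 3, of basal mammary markers 5 and 6, of luminal markers 3 and 2 and of Notch 3 and 2; the others had the same counts. The camera adjusted p of these lists lay between 0.149 and 0.871. Without the 50K array it was 0.00114 for NF-kB targets and 0.0356 for lysosome genes, and without the 800K array 0.0307 for wound-edge proteases. Among the lists that camera did not pass, the exact permutation of the list mean passed for fibroblast (adjusted p = 0.0185), leukocyte (0.0128) and adipocyte (0.0244) markers, luminal markers (0.0185), Wnt (0.0128), lysosome genes (0.0128), glycolysis (0.0453) and the NRF2 list (0.0453). Markers of other cell types did not pass camera as lists: of the fibroblast markers 2 rose and 2 fell (COL6A3, −0.71 ± 0.16, but −0.35 with an adjusted p of 0.0937 without 50K), of the endothelial markers 2 rose and 1 fell, of the leukocyte markers 1 rose (CD14, 0.74 ± 0.08), and of the adipocyte markers 1 fell (PPARG, −0.12 ± 0.02). Mean and test were negative and the median positive for the basal lamina (median 0.00235), fibroblast (0.00262) and adipocyte (0.00192) lists, and for the cAMP list mean (0.0014) and median were positive and the test negative. The call of COL6A3 was also lost without 100K, 400K or 600K (adjusted p 0.0544, 0.0524 and 0.0706), that of MME without 100K, 400K, 600K or 800K (up to 0.104) and that of SLC2A3 without 100K (0.0505). Of the counts of 3 or more, those of falling genes of the basal lamina were 2 without 50K, 100K or 600K and 3 without 400K or 800K, of basal mammary markers 1 without 50K or 600K and 2 without 100K or 800K, and of wound-edge proteases 2 without 50K and 3 without 100K, 600K or 800K. Those of rising genes were 5 for hypoxia without 400K, 1 for cholesterol synthesis and for Notch without 50K, 3 for NF-kB without 100K or 600K, and for the EGF receptor family 1 without 600K and 2 without 50K or 800K.

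Among genes fixed as checks of the line, GAPDH had a slope of 0.02 ± 0.01 (adjusted p = 0.464) and EGFR −0.06 ± 0.02 (adjusted p = 0.12). ACTB fell slightly (−0.07 ± 0.02, adjusted p = 0.0361), and the basal keratins KRT5 (0.12 ± 0.02) and KRT14 (0.42 ± 0.02) rose; the call of ACTB was lost without any array but 50K (adjusted p up to 0.142). As a sign of RNA quality, the 3′ minus 5′ difference of the ACTB control probe sets rose by 0.32 ± 0.06 log2 units from 50K to 800K, and that of GAPDH changed by −0.03 ± 0.05. The median ribosomal RNA control probe set was 1.43-fold higher on the 50K array than on the 100K array and between 1.43-fold and 1.60-fold higher than on each of the other arrays. The median of the 24 poly-A controls, added before labelling, had ratios of 0.835, 0.732, 0.759, 0.788 and 0.85 from 100K to 800K. Without the 50K array, 2989 genes had a density trend.

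Asked without any model of the scatter, 1279 genes rose or fell at every one of the 5 steps, 580 rising and 699 falling. Random orders of the 6 arrays would give 54.9 on average, though genes share the arrays and their counts move together. Of these 1279, 1234 also had a density trend. Without the probe sets prone to cross-hybridisation 842 genes were strictly ordered. Departures from a line were tested with a quadratic term. In limma 0 genes passed, with a smallest adjusted p of 0.102, while 2496 genes had an unadjusted p under 0.05, where 988.8 is the average by chance. Genes share the 6 arrays, so such counts move together and the excess is no test of curvature. Robust variance estimates gave 0 genes that passed and 2429 with an unadjusted p under 0.05. In a set test of the quadratic term, chosen after the data were examined, 18 of the 40 lists passed camera at the preset correlation and 0 with an estimated correlation, with 10 at an unadjusted p under 0.05. The smallest values were those of DNA replication (adjusted p = 4.33e-23, and adjusted p = 0.214 with an estimated correlation) and G2/M (adjusted p = 4.37e-16, and adjusted p = 0.282 with an estimated correlation), both with a negative term. Among single genes the smallest p-values of the term belonged to AKR1C3 (quadratic term 0.86 ± 0.05), whose ratio was 1.24 at 200K and 5.32 at 800K, and to MRGPRX3 (1.77 ± 0.12), whose ratio was 0.394 at 200K and 1.80 at 800K.

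Between the ends of the series, 976 genes differed by 2-fold or more, 444 higher and 532 lower at 800K than at 50K. With 1 array each this difference has no replicate check, and 880 of these genes also had a density trend. Across neighbouring densities the number of genes that differed by 2-fold or more was 50 from 50K to 100K, 52 from 100K to 200K, 63 from 200K to 400K, 36 from 400K to 600K and 38 from 600K to 800K, where the last 2 steps cover 0.585 and 0.415 doublings. With 1 random probe set per gene these counts were 96, 102, 110, 69 and 64. The SD of the log2 differences over genes was 0.20, 0.19, 0.21, 0.19 and 0.17 in the same order. In the first step ACSF2 was 1.53 and FOS 1.31 log2 units higher, while HSD17B2 differed by −2.33 and COL6A3 by −1.95. In the next step TLR1 differed by 1.93, KRT15 by 1.68, SCG5 by −2.92 and INSC by −1.74. From 200K to 400K CHAC1 was 3.18 and LINC02806 2.54 log2 units higher, ARSI differed by −1.50 and EVA1A by −1.39. From 400K to 600K BLNK differed by 2.03, CYP4F3 by 1.61, PLCB4 by −1.41 and FST by −1.33. In the last step ANKRD20A5P differed by 1.85, SERPINB4 by 1.50, SLC7A11 by −1.70 and STC2 by −1.50. The first principal component held 74.5% of the variance over genes and ordered the 6 arrays by density.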

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

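The tests in this part were chosen after the results were seen, except the random orders of the density trend and of the curvature, which were planned. Signals in data outside the gene comparisons were seen in 4 places. Of the 11721 non-control probe sets with no gene symbol in the annotation used here, 701 had a density trend when each probe set was tested alone, 391 rising and 310 falling. Of the 1801 probe sets with several symbols, 321 had one. These shares were 5.98% and 17.8%, against 16% of the probe sets with 1 symbol. The median of the 6 ribosomal RNA control probe sets was 1.43-fold higher on the 50K array than on the 100K array, and that of the 24 poly-A controls was 1.2-fold higher. In 20 random orders of the arrays the highest count over all non-control probe sets was 0. The order that exchanged neighbouring densities and gave 2063 genes in the gene test was not among these 20.

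The first pattern is the number of genes with a density trend. Of 100 orders of the 6 cell numbers, the real one included, 1 gave a count as large, the real one with 4220. The highest other, which exchanged neighbouring densities, gave 2063. A random order is therefore argued against, though 1 in 100 is the smallest share that these orders allow. For trends of 2-fold or more, a loss of 5′ signal could be checked only on ACTB and GAPDH. The 3′ minus 5′ difference of ACTB rose by 0.317 ± 0.0617 log2 units, the direction of such a loss, and that of GAPDH changed by −0.0347 ± 0.0476. Both changes are under 2-fold, but 2 transcripts do not bound the loss in others, so this stays open. A drift of hybridisation is argued against for trends of 2-fold or more, since the largest fitted change among 18 hybridisation controls was 0.255. Smaller trends are not covered by this bound. A drift of labelling stays open, since the largest fitted change among the 24 poly-A controls was −0.778 ± 0.43 log2 units. With this error a 2-fold change is not excluded. The median poly-A ratio did not fall steadily with density: it was 0.835 at 100K, 0.732 at 200K and 0.85 at 800K. The order of handling is not given in the sources used here. If it followed the sample numbers, it could not be told apart from density. For curvature the real count was 0, which 100 of the 100 orders reach by construction, so these orders say nothing about chance; the highest other count was 4101, in an order that turns the density gradient into a bend.

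The second pattern is the rise of the ATF4 and amino acid list at 400K. All 21 members lay above the line between their 200K and 600K values, by 0.55 log2 units on average, and 16 were highest at 400K, as CHAC1 at 11.5, SESN2 at 3.64, TRIB3 at 3.35 and STC2 at 2.92 times the 50K value. The other 39 lists had a median departure of −0.00428, with a highest value of 0.239, so none departed as much. These lists cannot decide on a shift of the whole array. RMA normalizes between arrays and the median ratio at 400K was 1.013, so such a shift would have been largely removed beforehand. A fault of the 400K dish or array alone is argued against by the 600K array, where, with 400K left out, the list mean lay 0.562 above the line between 200K and 800K, against 0.201 for the highest other list. The members differed after 400K, and 4 were highest at 600K. At 800K PHGDH was still 4.39 and ASNS 2.82 times the 50K value, while SLC7A11 was 0.353 and STC2 0.412 times it. As a hypothesis, genes of the amino acid response may rise between 200K and 400K and some of them fade at 800K, while the NRF2 list departed by 0.01 at 400K. With 1 array per density, a difference in handling shared by the 400K and 600K samples stays open.

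The third pattern is the timing of the falls: by 200K the replication list had reached 11.5% of its change between 50K and 800K, the YAP/TAZ list 42.1%, the mesenchymal list 70.3% and the TGF-beta list 80.6%. The means of the last 3 lists include members that rose. By 400K the mesenchymal and TGF-beta means had passed their 800K values (102% and 109%), which enlarges their shares. The 32 falling genes of these 3 lists had reached a median of 50.6% by 200K. On log2 of the cells, 200K lies at 2 of the 4 doublings, so a straight fall reaches about this share there. In their median these fallers, called by a linear slope, thus followed the line. The replication genes, with a median of 13.4%, fell later than it. These shares start from the 50K array. A deviation of that array alone is argued against as the whole cause by the fallers called without it. Of these, 25 of the 3 lists had reached a median of 30.6% of their change between 100K and 800K by 200K, against 6.52% (SD 6.51, 22 genes) for the replication genes. A straight fall from 100K would also give a share near that of the 3 lists. On the same range the list means had reached 6.23% for replication, 26.3% for YAP/TAZ, 56.9% for mesenchymal genes and 62.3% for TGF-beta. The TGF-beta list did not pass camera without 50K (adjusted p = 0.198). Values that reach the background would flatten early, and this stays open: 22 falling genes of these 3 lists whose 800K ratios lay within the range of the replication genes had reached a median of 50.8% by 200K, against 13.4% (SD 7.34, 25 genes) for the replication genes, but a match on the ratio is no match on signal over background, which the ratios do not hold. A chance order of the arrays stays open too: in exact permutations the curvature of the difference from the replication list gave p = 0.0722 for YAP/TAZ, 0.133 for TGF-beta and 0.224 for mesenchymal genes, with adjusted values of 0.2, 0.2 and 0.224. That contact and spreading genes may respond at lower densities than the cell cycle is therefore a hypothesis that these 6 arrays do not settle.

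The number of genes that differed between the 3 lowest and the 3 highest densities was 2259 in limma, and the highest among the other 9 splits was 0. With 10 splits in all, of which 1 gave a count as large, the share cannot fall under 0.05.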

How the results depend on the processing

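Drawing 1 probe set per gene at random and robust variance estimates were chosen after the data were examined. No paired analysis was possible because each density has 1 array. Filters on the mean level, the brightest probe set per gene, quantile normalization and a mean-variance trend were not run, since ratios hold no level; no filter, the mean of all probe sets and no trend became the settings reported. The count of 4220 genes with a density trend was 2664 (1157 rising, 1507 falling) without probe sets prone to cross-hybridisation, where 17098 genes were tested, and 2259 (908 and 1351) for the 3 lowest against the 3 highest densities. Leaving out each array gave 2388 to 3909 (1026 to 1627 rising, 1362 to 2282 falling), the lowest without 800K and 2447 without 600K, fits with fewer arrays. Centring gave 4001, with 90.1% of the calls kept and 38.2% rising against 41.8%. The cell number itself gave 4470, its rank 4551, robust variance 4075 and a random probe set 3274. Strictly ordered genes numbered 842 without the probe sets prone to cross-hybridisation and 1925 to 2784 without 1 array, where random orders of 5 arrays give 330 on average. Curvature in limma gave 0 genes in every alternative run, with 1755 to 2719 at an unadjusted p under 0.05 without 1 array and 2051 on the cell number itself. With an estimated correlation 0 lists passed; leaving out each array gave 18 to 21 lists. With a random probe set the 2-fold counts per step were 96, 102, 110, 69 and 64, higher than with averaged probe sets; the cause was not tested. Of 1026 slopes of named genes under the alternatives other than leaving out an array, 921 kept direction and side of the threshold, 90 lost the call, 7 gained it and 8 turned; of 912 without 1 array the numbers were 812, 88, 7 and 5. The turned slopes were, without the probe sets prone to cross-hybridisation, TAGLN 0.0135, GDF15 −0.00550 and STC2 0.0615; with a random probe set, NRG1 0.00279, STC2 0.0615 and EGFR 0.00917; for the 3 lowest against the 3 highest densities, SLC7A11 0.264 and STC2 0.348; without 800K, SLC7A11 0.181, STC2 0.268, MRGPRX3 −0.0236 and SERPINB4 −0.0143; and without 50K, LEP 0.0193. Over the 6 left-out arrays these slopes ranged from −0.106 to 0.0193 for LEP, −0.0236 to 0.643 for MRGPRX3, −0.0143 to 0.326 for SERPINB4, −0.177 to 0.181 for SLC7A11 and −0.153 to 0.268 for STC2. The direction of the set test turned in lists that did not pass, with these mean slopes. Without the probe sets prone to cross-hybridisation they were −0.00724 for glycolysis, −0.00660 for NF-kB and −0.00185 for the EGF receptor family; on the cell number itself, −0.000109 for basal lamina and 6.38e-05 for cAMP; on ranks, 0.00563 for cAMP; for the 3 lowest against the 3 highest, 0.0179 for cholesterol and 0.0160 for cAMP. Without 50K they were −0.00468 for basal lamina, −0.00188 for cholesterol and 0.00591 for cAMP; without 600K, 0.00831 for cAMP; without 100K, 400K and 800K, 0.0553, 0.0546 and 0.0294 for immediate early genes; without 100K and 400K, −0.0580 and −0.0572 for fibroblast markers; and with fry, 0.0534 for immediate early genes. Over the 6 left-out arrays the mean slopes ranged from 0.0294 to 0.098 for immediate early genes, −0.0588 to −0.00468 for basal lamina, −0.00188 to 0.0487 for cholesterol, −0.0223 to 0.0118 for cAMP and −0.0658 to −0.0508 for fibroblast markers. The cause of these turns was not tested.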

Other observations

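Gene families defined by their symbols, chosen after the data were seen and tested with camera over 20 families, added groups that the lists did not hold. The mean slopes of the families named here kept their sign after centring the arrays. Of 13 alpha and beta tubulins 9 fell and none rose, with TUBA4A 6.02-fold and TUBB2A 4.13-fold lower at 800K than at 50K (camera adjusted p = 3.16e-05, and adjusted p = 0.49 with an estimated correlation). Of 8 subunits of the chaperonin that folds tubulin and actin, 5 fell, CCT2 by the most with a slope of −0.17 ± 0.03 (adjusted p = 0.00749, and adjusted p = 0.49 with an estimated correlation); without 100K, 600K or 800K 3, 2 and 2 fell. Of 14 kallikrein peptidases 6 rose and none fell, among them KLK7 (7.75-fold), KLK10 (7.76-fold) and KLK11 (7.16-fold), with an adjusted p of 0.000328, and adjusted p = 0.49 with an estimated correlation. Of 18 aldehyde dehydrogenases 9 rose and 1 fell (adjusted p = 0.00136, and adjusted p = 0.49 with an estimated correlation), with ALDH3A1 3.91-fold higher at 800K; without 600K or 800K 5 rose. The other 4 families that passed overlap with the lists: 11 of 19 GINS, MCM and ORC subunits fell (adjusted p = 1.56e-07), 10 of 38 kinesins fell and KIF13B rose (0.00769), 6 of 19 S100 proteins rose (0.00559), and 7 of 44 keratins rose and 2 fell (0.0305), each with an adjusted p = 0.49 with an estimated correlation. Without 100K, 600K or 800K 3, 4 and 4 of the replication subunits fell, of the kinesins 5 fell without 50K, 100K or 600K and 6 without 800K, and of the keratins 1 fell without 50K or 100K and none passed in that direction without 600K or 800K.

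The remaining 12 families did not pass the test. Of 43 collagens 6 fell and 1 rose (adjusted p = 0.677), the fallers including COL8A1 (4.04-fold lower), COL16A1 (3.55-fold lower) and COL12A1 (2.96-fold lower at 800K); their mean slope was −0.05 and their median 0.00418. Of 21 ephrins and Eph receptors 6 rose and 2 fell (adjusted p = 0.0539), with EPHB3 3.01-fold and EFNA1 2.83-fold higher and EPHA2 2.41-fold and EFNB2 2.18-fold lower at 800K. In the NRF2 list AKR1B10 and AKR1C3 rose while the list as a whole had a median slope of −0.02. Probe sets can cross-hybridise between members of a family, so single paralogs are uncertain.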
